A study of Homo sapiens with 23 samples.

How the data were processed

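Polyadenylated RNA of 23 libraries of HUDEP-2 cells, an established human erythroid line, was extracted with Trizol and sequenced, per the labels' protocols, which state 1 µg of total RNA per library. The deposited values are raw read counts per gene, made by the authors with featureCounts, per the file headers. The headers name featureCounts 1.6.0 and the GENCODE 28 annotation for the knockdown files, and featureCounts 2.0.1 and GENCODE 39 for the knockout and construct files. The submitters' processing notes name HISAT2 2.2.1, SAMtools 1.18, featureCounts 2.0.1, DESeq2 1.34.0 and build GRCh38, so for the knockdown the counter's version differs between header and notes. In the commands of the headers, reads were summed over exons of a gene, without a strand option, without counting fragments, and leaving out reads that map to several places or overlap several genes. Antisense and overlapping genes therefore cannot be told apart, and near-identical gene copies lose reads. The headers of the 6 knockout and WT files also carry the terms slamseq and IAA, which the labels do not explain. If those libraries were labelled and alkylated, base changes in the reads could alter how many were aligned, and this was not tested.

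Gene identifiers were paired with symbols from the gene name table for 57754 of 58381 identifiers in the knockdown (98.93%) and 61369 of 61533 in the other experiments (99.73%). Total counts per library were 32291312 to 35338030 in the knockdown, 28054018 to 30717782 in the knockout and 27681786 to 32274208 in the construct experiment. Counts on the mitochondrial chromosome were 0 in every library, so the list of mitochondrially encoded genes was not measured. No replicates were duplicates of each other: the chi-square of counts divided by its degrees of freedom was 3.9 to 6.77 between knockdown replicates, 8.88 to 51.9 in the knockout and 18.8 to 76.1 in the construct experiment. Reads of PCR-amplified libraries without molecular identifiers are not independent molecules, so the floor of 3 counts used for genes at 0 covers counting error only.

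Groups and replicate numbers were taken from the sample labels. The knockdown (9 libraries), knockout (6) and construct (8) experiments were fitted separately. Each has its own control libraries, and the knockdown files use another annotation than the rest. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The mean of both hairpins, each hairpin, the difference between hairpins, the knockout, both constructs at 24 h against 0 h, the difference of these responses, and the constructs at 0 h made 9 comparisons. Residual degrees of freedom were 6, 4 and 4, and the biological coefficient of variation was 5.06%, 16.8% and 15.5% in the knockdown, knockout and construct experiments.

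Gene groups were 30 lists of pathways, red cell genes and markers of other cell types, of which 29 had enough measured members (at least 3). They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Counts of called members are given over all genes tested and, where different, adjusted over the list alone. KIT and GATA2 stand in several lists, as do other genes, so the lists are not independent. Overlaps of calls were set beside n1 × n2 / N and, for the hairpins, beside 20 simulations of unchanged groups sharing simulated shGFP libraries. Signs of genes called in 2 comparisons were tested with Fisher's exact test, two-sided, over genes, which are not independent replicates.

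The rule for naming genes, the design of the 9 comparisons and the lists were fixed before the data were examined, and tests added later are named in the closing section. The rule named TENT5C and its family, the globin genes, ALAS2, SLC4A1, KIT, GATA1, GATA2 and 1 gene not reported here everywhere, the 10 largest rises and falls (5 in lesser comparisons) among called protein-coding genes with at least 5 CPM in the higher group and replicates that did not overlap, and up to 4 members per list with the smallest p. Of the 10 largest rises with the FAM46C construct, 1 gene belongs to a near-identical gene pair and is not described.

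The alternatives were DESeq2 1.42.0, RLE factors, scaling by total counts, TMM without globin and mitochondrial genes, no count filter, a stricter filter (1 CPM and 50 counts), a 2-fold threshold, only the groups compared, the replicate number as a block, and leaving out each library. Those added after the data were seen are named in the closing section. The test was tried on simulated counts with 200 changed genes. It recovered 88.7%, 95.8% and 100% of 1.5-, 2- and 4-fold changes in the mean of both hairpins (15781 genes), 40%, 81.5% and 98.8% in the knockout (12424 genes), 12.9%, 65.8% and 90.3% with the FAM46C construct and 3.2%, 34.2% and 83.9% for the difference of responses (15324 genes each). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.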

Results

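Messenger RNA was sequenced from 23 libraries of HUDEP-2 cells, an immortalised human erythroid progenitor line that can be matured towards red cells in culture. FAM46C, listed in the annotation as TENT5C, is a cytoplasmic enzyme that lengthens the poly(A) tails of messenger RNAs. The libraries were made from polyadenylated RNA and tail length was not measured. A change in counts therefore need not be a change in the amount of a messenger. In a knockdown experiment, 3 libraries came from cells with a control hairpin against GFP (shGFP), 3 from cells with hairpin shFAM46C_2 and 3 from cells with hairpin shFAM46C_3. In a knockout experiment, 3 libraries of wild-type cells (WT) stood beside 3 libraries of FAM46C knockout cells labelled 2B11. The file headers of these 6 libraries carry the term slamseq, a method that sequences metabolically labelled RNA after alkylation, while the labels do not mention it, so it is open whether their counts come from plain RNA sequencing. In a construct experiment, cells labelled as knockout 2B11 carried a doxycycline-controlled FAM46C construct or a mutant of it labelled 9092mut, and each was sampled after 0 h and 24 h of doxycycline with 2 libraries per group. Total counts per library were 32291312 to 35338030 in the knockdown, 28054018 to 30717782 in the knockout and 27681786 to 32274208 in the construct experiment. Levels are CPM, counts scaled to a common library size by the trimmed mean of M-values (TMM), with the SD between libraries, and fold changes come from the fitted model with the standard error (SE) of the log2 value. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

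TENT5C (ENSG00000183508, chromosome 1, 117605934 to 117628372 in the annotation of the knockdown files, GRCh38) was read in every library to check the labels. It stood at 223 ± 11 CPM with shGFP (SD, n = 3), 80.3 ± 1.5 CPM with shFAM46C_2 and 79.1 ± 2.4 CPM with shFAM46C_3. WT libraries held 40.6 ± 2.1 CPM and knockout libraries 7.55 ± 2.0 CPM (n = 3 each), a 5.37-fold lower level that left some reads of the gene. In the construct experiment TENT5C rose from 809 ± 31 to 12370 ± 340 CPM with the FAM46C construct and from 409 ± 9.8 to 8346 ± 800 CPM with the mutant (n = 2 each). Reads of the construct and of the gene were not separated, and at 0 h both constructs already gave more TENT5C than the WT libraries of the other experiment, a level set across separately prepared libraries. The related genes TENT5A, TENT5B and TENT5D lay lower in all experiments, TENT5A being the highest of them at 25.1 ± 2.3 CPM with shGFP.

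**Figure D1:**
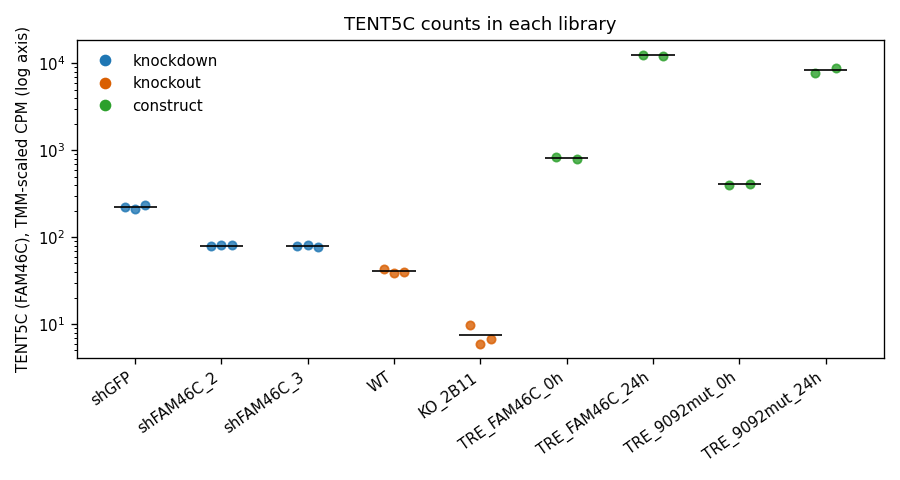
TENT5C level in each of the 23 libraries by group, as TMM-scaled CPM on a log axis, with points for libraries and bars for group means. Every hairpin library (76.59 to 81.59 CPM) lies below every shGFP library (211.2 to 232.3 CPM), and both constructs rise between 0 h and 24 h.

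The knockdown asked which messenger RNAs change when FAM46C is lowered in HUDEP-2 cells. Red cell genes fell as a group with the mean of both hairpins. Of 31 measured genes of the red cell membrane and blood groups, 26 fell and 1 rose, among them KEL (2.09-fold lower), the cytoskeletal protein gene DMTN (2.14-fold lower) and ANK1, which anchors the membrane to the cytoskeleton (1.72-fold lower). SLC4A1, the anion exchanger band 3, went from 466 ± 12 CPM to 239 ± 24 CPM and 336 ± 20 CPM with hairpins shFAM46C_2 and shFAM46C_3. Of 27 haem and iron genes, 21 fell and 3 rose. ALAS2, which catalyses the rate-limiting step of erythroid haem synthesis, fell 2.29-fold (log2 -1.20 ± 0.04), and CPOX, a later enzyme of that pathway, fell 2.97-fold. ALAD fell 3.27-fold, and SLC25A37, the mitochondrial iron importer, fell from 2492 ± 36 to 919 ± 49 and 1186 ± 45 CPM.

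Transcription factors of the red cell programme went the same way, with 19 of 22 lower and 2 higher. GATA1 fell 1.71-fold, KLF1 1.81-fold, GFI1B 1.99-fold and TAL1 1.62-fold. Genes of terminal erythroid maturation were lower in 32 of 37 and higher in 3, with HEMGN 3.03-fold, SELENBP1 2.2-fold and CA1, the red cell carbonic anhydrase, 1.9-fold lower. Adult globin messengers fell too, HBB 1.58-fold from 12970 ± 291 CPM and HBA2 2.0-fold, while HBD rose 1.41-fold. HBA1 and HBA2 are near-identical copies whose reads cannot be assigned with certainty, and the same holds for the pair RHD and RHCE. Of 8 measured globin genes 6 fell and 1 rose, and globin genes took 1.42 ± 0.045% of all counts with shGFP against 0.795 ± 0.086% and 0.994 ± 0.040% with the hairpins. KIT, the stem cell factor receptor of early progenitors, rose 1.33-fold, whereas GATA2 stayed at 620 ± 38, 627 ± 22 and 569 ± 3.1 CPM (log2 -0.06 ± 0.03, not past the test).

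Camera called the membrane (adjusted p = 7.27e-21), haem and iron (7.04e-20), transcription factor (6.17e-16) and maturation (1.83e-15) lists lower, with Benjamini-Hochberg adjustment over 29 lists. With an estimated correlation the adjusted p was 0.0228 for the membrane, haem and maturation lists and 0.0133 for the transcription factors. For shFAM46C_3 alone the adjusted p with an estimated correlation was 0.0876 for the membrane, 0.0908 for the haem and iron and 0.0808 for the maturation list, so these calls were lost, and 0.0279 for the transcription factors. For shFAM46C_2 alone all 4 held (adjusted p = 0.0272, 0.0272, 0.0332 and 0.0126 with an estimated correlation). TENT5C is itself a maturation gene of that list, whose adjusted p was 3.87e-13 without it. The globin list was called by camera (adjusted p = 0.00135) and lost with an estimated correlation (adjusted p = 0.297), and camera did not call it for shFAM46C_3 alone (adjusted p = 0.0639). In the red cell lists the counts adjusted over the list alone were the same as those over all genes tested.

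Interferon-stimulated genes also fell as a group. Of 40 measured members 34 fell and 3 rose, with a median log2 fold change of -0.95. IFIT3 fell 2.97-fold, IFIT1 2.4-fold, HERC5 2.64-fold and OASL 3.84-fold, from 41.9 ± 2.3 to 7.68 ± 0.091 and 15.5 ± 1.2 CPM. Camera gave an adjusted p of 9.96e-17 for this list and an adjusted p of 0.0326 with an estimated correlation, which was 0.0332 for shFAM46C_2 and 0.114 for shFAM46C_3 alone. Cell cycle genes were lower in 39 of 52 and higher in 6, with a median log2 fold change of -0.229 (camera adjusted p = 2.99e-07, adjusted p = 0.0654 with an estimated correlation). The replication factor MCM4 was 1.42-fold lower and the cyclin CCNB2 2.92-fold lower.

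Genes of protein folding in the endoplasmic reticulum rose. Of 39 such chaperones and stress-response genes, 28 rose and 3 fell, 29 rising when adjusted over the list alone, with the chaperone HSPA5 1.85-fold and the translocon-associated SSR3 2.51-fold higher (camera adjusted p = 5.3e-10, adjusted p = 0.0228 with an estimated correlation). Immediate early and heat shock genes rose in 17 of 28 and fell in 7, EGR1 4.04-fold and IER3 4.19-fold higher (camera adjusted p = 3.63e-05, and an adjusted p of 0.0228 with an estimated correlation). With an estimated correlation this list held for shFAM46C_2 alone (adjusted p = 0.0126) but not for shFAM46C_3 alone (adjusted p = 0.0946). With shFAM46C_3, 15 were higher and 9 lower, or 16 and 10 when adjusted over the list alone. EGR3 rose 11.1-fold from 0.636 ± 0.21 CPM. The list of ribosome biogenesis genes, which also holds MYC and MYC-linked genes, rose in 24 of 35 and fell in 3 (camera adjusted p = 8.4e-06, adjusted p = 0.086 with an estimated correlation). ODC1, a MYC-linked member that makes polyamines, was 4.42-fold higher. Nuclear genes of oxidative phosphorylation rose in 44 of 76 and fell in 8, or 9 when adjusted over the list alone, COX6B1 2.78-fold and COX5A 2.06-fold higher (camera adjusted p = 0.00213, adjusted p = 0.562 with an estimated correlation). Median log2 fold changes were 0.372 for the chaperone, 0.378 for the immediate early, 0.219 for the ribosome biogenesis and 0.151 for the oxidative phosphorylation list. The genes named here moved further than the median of their list.

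Of the 4 lists for other blood lineages, 2 were called higher by camera, and neither call held with an estimated correlation. Mast cell, basophil and eosinophil genes, a list that also holds the progenitor genes KIT and GATA2, rose in 9 of 11, among them HPGDS 1.91-fold and ENPP3 1.86-fold higher. Granulocyte and monocyte genes rose in 8 of 11, and in 9 when adjusted over the list alone, with CEBPA, a myeloid transcription factor, going from 0.838 ± 0.19 to 4.51 ± 0.59 and 2.05 ± 0.33 CPM. The mast cell list had a camera adjusted p of 0.00462 and an adjusted p of 0.225 with an estimated correlation, and the granulocyte list a camera adjusted p of 0.0267 and an adjusted p of 0.112 with an estimated correlation, and camera did not call the granulocyte list for shFAM46C_3 alone (adjusted p = 0.0753). The remaining 16 lists were not called by camera, the lowest adjusted p among them being 0.0956 for stem and progenitor genes (15 of 25 higher, 7 lower). Several of these held many genes moving both ways, such as the lysosome (20 of 54 higher, LAMP1 2.36-fold, and 19 lower) autophagy (15 of 45 higher, MAP1LC3B 2.67-fold, and 17 lower), glycolysis and hypoxia (12 of 30 higher, 12 lower), p53 targets (9 of 26 higher, 10 lower), the ATF4 response (9 of 31 higher, 13 lower), cholesterol synthesis (12 of 25 higher, 7 lower), ribosomal proteins (41 of 78 higher, 11 lower) and genes targeted to the endoplasmic reticulum (10 of 32 higher, 18 lower). Proton pump genes (5 of 16 higher, 5 lower), cell cycle inhibitors (4 of 14 higher, 7 lower), poly(A) tail metabolism (7 of 35 higher, 13 lower), histones (7 of 42 higher, 1 lower), megakaryocyte (5 of 12 higher, 2 lower), lymphoid (3 of 7 higher, 1 lower) and stromal genes (1 of 8 higher, 3 lower) were also uncalled. Adjusted over the list alone, the numbers higher and lower were 16 and 7 for stem and progenitor genes, 21 and 20 for the lysosome, 12 and 13 for glycolysis and hypoxia, and 10 and 19 for genes targeted to the endoplasmic reticulum. They were 5 and 7 for cell cycle inhibitors, 5 and 0 for histones and 2 and 3 for stromal genes. With a single hairpin, camera called some of these 16 lists. ATF4 response (adjusted p = 0.0202) and endoplasmic reticulum-targeted genes (0.0225) were lower with shFAM46C_2. Lysosome (0.0267), glycolysis and hypoxia (0.0376) and ribosomal protein genes (9.47e-06) were higher with shFAM46C_3. None of these calls held with an estimated correlation.

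Single genes moved further than these groups. CDHR1 (chromosome 10, 84194635 to 84219621), a cadherin-related gene, fell from 138 ± 4.5 to 12.4 ± 2.2 and 23.1 ± 1.1 CPM, a log2 fold change of -3.02 ± 0.06 (adjusted p = 2.46e-27 in edgeR's quasi-likelihood test). The aspartic protease gene CTSE fell 7.3-fold, CREB3L3 7.76-fold, KRT13 5.05-fold and PCYT1B 4.87-fold. CCL1, a chemokine gene on chromosome 17 (34360328 to 34363231), stood at 0.059 ± 0.058 CPM with shGFP, 11.4 ± 1.6 CPM with shFAM46C_2 and 9.19 ± 1.1 CPM with shFAM46C_3, and no fold is given because its shGFP level rests on a handful of counts. GAS7 rose 8.13-fold, VGF 7.51-fold, GEM 6.93-fold and RRAS 6.0-fold. EVI2A (8.91-fold) and EVI2B (13.2-fold) also rose, but they lie inside another gene and the counting did not use strand, so their reads are uncertain. CCL3L3 rose 11.5-fold and belongs to a family of near-identical chemokine genes, which makes its own level uncertain.

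In all, 8810 of 16174 tested genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 for the mean of both hairpins, 4370 higher and 4440 lower, and 1392 of them by at least 2-fold. Replicates in this experiment differed little (biological coefficient of variation 5.06%), so many calls were of small size. Hairpin shFAM46C_2 alone changed 8960 genes (4522 higher, 4438 lower) and shFAM46C_3 alone 7977 (4134 higher, 3843 lower), of which 1809 and 1221 by at least 2-fold. Called with both were 6099 genes, and 5339 of these (87.5%) had the same direction, 2831 higher and 2508 lower. Independent lists of these sizes would share 2210.3 genes in the same direction (1155.8 higher and 1054.5 lower). In 20 simulations both hairpin groups and their shared controls were drawn from the shGFP levels, and each gave 0. No group was shifted there, so a common shift of the real shGFP libraries from both hairpins is not covered. Across genes, which are not independent replicates, the log2 fold changes of the hairpins correlated at r = 0.713 against 0.502 in the simulations, with a covariance of 0.354 against 0.0284. The 3 control libraries cannot be split with 2 in each part, so part of the excess may come from the shared controls.

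The hairpins lowered TENT5C alike (80.3 ± 1.5 and 79.1 ± 2.4 CPM, log2 difference -0.02 ± 0.04), yet the remaining genes differed widely between them. Comparing shFAM46C_3 directly with shFAM46C_2, 7285 genes passed the test, 3705 higher and 3580 lower with shFAM46C_3, and 836 by at least 2-fold. Red cell membrane genes were higher with shFAM46C_3 in 20 of 31 and lower in 6, or 7 when adjusted over the list alone. Haem and iron genes were higher in 18 of 27 and lower in 3, or 4 when adjusted over the list alone, with ABCB10 at 266 ± 13 against 80.7 ± 4.5 CPM and ALAS2 at 260 ± 6.0 against 134 ± 14 CPM. The cyclin CCNB2 stood at 170 ± 5.3 CPM with shFAM46C_3 and 37.6 ± 1.3 CPM with shFAM46C_2, against 233 ± 5.4 CPM with shGFP. The chaperone HSP90B1 rose 3.38-fold with shFAM46C_3 and was at 235 ± 8.7 CPM with shFAM46C_2 against 214 ± 5.6 CPM with shGFP. NTS, the neurotensin gene (chromosome 12, 85874295 to 85882992), was at 77.8 ± 5.1 CPM with shFAM46C_3 and 7.0 ± 0.94 CPM with shFAM46C_2. The metallothionein gene MT2A went the other way, at 4.92 ± 0.40 against 42.5 ± 6.4 CPM.

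Camera called 12 of 29 lists between the hairpins, and 2 of them held with an estimated correlation. These were cholesterol synthesis (16 of 25 lower with shFAM46C_3, INSIG1 2.07-fold, camera adjusted p = 3.18e-05) and immediate early and heat shock genes (17 of 28 lower, 18 when adjusted over the list alone, EGR1 1.94-fold and JUN 2.22-fold, camera adjusted p = 3.18e-05), each with an adjusted p of 0.0457. Ribosomal protein genes were higher with shFAM46C_3 in 71 of 78, RPL10 1.84-fold and RPL13A 1.76-fold, at a camera adjusted p of 2.26e-10 and an adjusted p of 0.398 with an estimated correlation. Against shGFP, this list was higher in 59 of 78 and lower in 1 with shFAM46C_3 (60 higher when adjusted over the list alone, camera adjusted p = 9.47e-06, adjusted p = 0.504 with an estimated correlation). With shFAM46C_2 it was higher in 13 and lower in 27, and camera did not call it (adjusted p = 0.341).

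**Figure D2:**
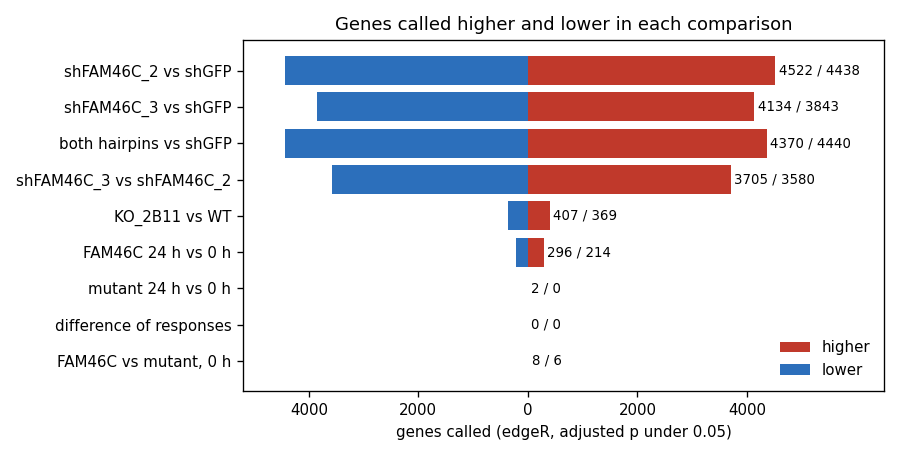
Number of genes higher (above 0) and lower (below 0) in each comparison at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The knockdown comparisons hold 7285 to 8960 genes, the knockout 776, the FAM46C construct 510 and the mutant construct 2.

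The knockout experiment asked what the loss of FAM46C does in a clone of the same line. Red cell genes as groups were not called there. In the knockout libraries 1 of 30 red cell membrane genes was higher and 1 lower, SLC4A1 at 33.6 ± 0.35 against 49 ± 7.2 CPM (1.46-fold lower) and RHD 2.2-fold higher, with 3 higher and 1 lower when adjusted over the list alone and a camera adjusted p of 0.485. Of 27 haem and iron genes 3 fell, 4 when adjusted over the list alone, ALAD 1.53-fold, the transferrin receptor gene TFRC 1.42-fold and FAM210B 1.33-fold (camera adjusted p = 0.484). ALAS2 was at 364 ± 22 against 327 ± 13 CPM, GATA1 at 302 ± 25 against 341 ± 77 CPM and HBB at 6556 ± 478 against 6416 ± 1161 CPM, none past the test. HBD rose 2.2-fold to 210 ± 7.1 CPM, while the fetal globins HBG1 and HBG2, near-identical copies with uncertain reads, were lower at 0.161 ± 0.032 against 0.748 ± 0.14 CPM and 0.225 ± 0.084 against 2.72 ± 0.66 CPM. KIT rose 1.64-fold from 48.5 ± 10 to 79.6 ± 9.6 CPM.

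Other groups did differ between the clone and WT. Replication-dependent histone genes fell in 6 of 32 and rose in none, H2BC12 2.3-fold and H1-2 2.73-fold lower, although histone messengers mostly lack poly(A) tails and their gene copies share reads (camera adjusted p = 2.64e-06, adjusted p = 0.102 with an estimated correlation). Mast cell, basophil and eosinophil genes fell in 6 of 12, 7 when adjusted over the list alone, and rose in 1, which was KIT, HPGDS being 3.33-fold and the tryptase gene TPSB2, which has a near-identical copy, 1.65-fold lower (camera adjusted p = 7.84e-05, adjusted p = 0.102 with an estimated correlation). Stromal and endothelial genes fell in 2 of 7, the intermediate filament gene VIM from 799 ± 62 to 190 ± 15 CPM and SPARC from 2.87 ± 0.35 to 0.427 ± 0.35 CPM (camera adjusted p = 9.56e-06, adjusted p = 0.102 with an estimated correlation). Genes of the amino acid stress response controlled by ATF4 rose in 7 of 28, in 9 when adjusted over the list alone, where 1 fell, with the amino acid transporter SLC7A5 1.96-fold and the serine synthesis enzyme PSAT1 1.75-fold higher (camera adjusted p = 0.000331, adjusted p = 0.143 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 25, in 6 when adjusted over the list alone, DHCR7 1.53-fold (camera adjusted p = 0.0149, adjusted p = 0.183 with an estimated correlation).

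Ribosomal protein genes were called lower by camera (adjusted p = 5.52e-11, median log2 -0.28) though 1 of 78, RPL13A, passed on its own and 0 when adjusted over the list alone, and the adjusted p was 0.793 with an estimated correlation. Their share of all counts was 13.9 ± 0.73% in the clone and 15.6 ± 1.41% in WT. Oxidative phosphorylation genes had a camera adjusted p of 0.000345 for lower levels and an adjusted p of 0.804 with an estimated correlation, with 0 of 75 members called by edgeR. The other 22 lists were not called, the lowest adjusted p being 0.299. Interferon-stimulated genes were among them, with 2 of 29 higher, HERC6 at 5.96 ± 1.0 against 1.46 ± 0.56 CPM and HERC5 at 7.91 ± 0.47 against 3.15 ± 1.2 CPM.

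The largest single changes in the clone were near-complete losses. GALNT14 (ENSG00000158089, chromosome 2, 30910467 to 31155202), which starts O-linked sugar chains, went from 14.8 ± 1.9 to 0.108 ± 0.14 CPM. TMEM273 went from 10.7 ± 2.0 to 0.15 ± 0.097 CPM, the carbonic anhydrase gene CA3 from 10.5 ± 1.2 to 0.162 ± 0.15 CPM, the progesterone receptor gene PGR from 11.1 ± 2.3 to 0.214 ± 0.097 CPM and CCDC22 from 6.71 ± 1.5 to 0.151 ± 0.15 CPM. REC8, a meiotic cohesin gene, fell 25.3-fold from 38.4 ± 3.0 CPM (log2 -4.66 ± 0.23, adjusted p = 3.46e-11 in edgeR's quasi-likelihood test). Among the rises were the kinase gene FYN (ENSG00000010810, chromosome 6, 111660332 to 111873452), 13.6-fold from 0.75 ± 0.10 CPM, RFTN1 10.4-fold, the alkaline phosphatase gene ALPL 6.8-fold and the growth factor receptor gene FGFR1 4.96-fold.

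Of 12688 tested genes 776 passed the test, 407 higher and 369 lower in the clone, 280 by at least 2-fold. This count rests on single libraries, being 382, 439 and 423 without knockout replicates 1, 2 and 3, 454 without WT replicate 2 and 2173 without WT replicate 3. With scaling by total counts, 613 genes were higher and 251 lower. Among 537 genes called in both the knockout and the knockdown, 280 (52.1%) had the same sign, where independent lists would share 239.4, and the odds ratio of the signs was 1.15 (Fisher's exact test, two-sided p = 0.434). Without WT replicate 3 the number with the same sign was 823 of 1510, and the odds ratio of 1.42 passed Fisher's exact test (two-sided p = 0.000898). Without WT replicate 1 it was 257 of 580, and the odds ratio of 0.633 passed the same exact test the other way (two-sided p = 0.00737). The number was 121 of 263, 143 of 301 and 149 of 292 without knockout replicates 1, 2 and 3, and 150 of 305 without WT replicate 2.

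**Figure D3:**
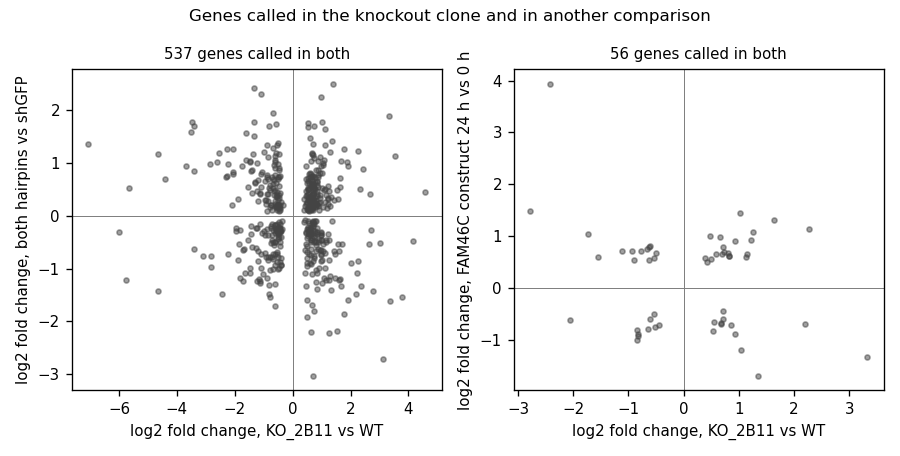
Log2 fold changes of the genes called in 2 comparisons, for knockout against knockdown (537 genes) and for knockout against the FAM46C construct (56 genes), each point being a gene. The points fill all 4 quadrants, with 280 of 537 in the quadrants of equal sign and 26 of 56 in those of opposite sign.

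The construct experiment asked what changes with 24 h of doxycycline in cells that carry the FAM46C construct, with the mutant construct as the comparison. TENT5C was already at 809 ± 31 CPM at 0 h, so the change is a further rise and not a start from absence. Red cell membrane genes rose with the FAM46C construct in 7 of 30, and in 17 when adjusted over the list alone. EPB42 went from 106 ± 2.2 to 175 ± 21 CPM, TMOD1 from 43.3 ± 1.5 to 73.2 ± 3.6 CPM and SLC4A1 from 109 ± 2.6 to 162 ± 18 CPM (n = 2 each). Camera called this list higher (adjusted p = 4.66e-11, and an adjusted p of 0.0251 with an estimated correlation). Genes of terminal maturation rose in 3 of 35, in 10 when adjusted over the list alone, RAP1GAP 1.53-fold and RNF123 1.57-fold besides TENT5C itself (camera adjusted p = 1.18e-09, adjusted p = 0.0251 with an estimated correlation, and 1.33e-05 by camera without TENT5C). Of the haem and iron genes ALAD rose 1.75-fold as 1 of 27, with 8 when adjusted over the list alone (camera adjusted p = 0.00359, adjusted p = 0.51 with an estimated correlation). No globin gene passed the test, and ALAS2 (170 ± 49 against 166 ± 6.1 CPM) and GATA1 (216 ± 6.7 against 184 ± 14 CPM) did not either.

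The few progenitor and mast cell genes that passed the test fell, KIT and GATA2 standing in both lists. KIT went from 1037 ± 71 to 685 ± 63 CPM, GATA2 from 642 ± 22 to 456 ± 20 CPM and IKZF2 from 33.9 ± 3.8 to 13.4 ± 2.6 CPM, the 3 of 22 stem and progenitor genes that passed (6 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.514 with an estimated correlation). In the mast cell list 3 of 12 fell, KIT, GATA2 and EPX (5 when adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.169 with an estimated correlation). Genes of the ATF4 response rose in 7 of 30, in 12 when adjusted over the list alone, the glycine transporter gene SLC6A9 2.07-fold and the alanyl-tRNA synthetase gene AARS1 1.65-fold (camera adjusted p = 1.91e-09, adjusted p = 0.111 with an estimated correlation). Cell cycle genes rose in 6 of 52, in 16 with 1 falling when adjusted over the list alone, the mitotic kinase gene PLK1 from 219 ± 9.4 to 386 ± 2.9 CPM and KIF20A 1.8-fold (camera adjusted p = 7.05e-06, adjusted p = 0.11 with an estimated correlation). Autophagy genes rose in 3 of 44, in 5 when adjusted over the list alone, OPTN 1.65-fold and NBR1 1.48-fold (camera adjusted p = 0.00359, adjusted p = 0.111 with an estimated correlation). Genes of poly(A) tail metabolism rose in 3 of 34, in 7 when adjusted over the list alone, CNOT10 1.55-fold and PAN2 1.53-fold besides TENT5C, but the camera adjusted p of 0.0139 became 0.524 without TENT5C and was an adjusted p of 0.548 with an estimated correlation.

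Cholesterol synthesis genes had a camera adjusted p of 0.00324 for higher levels and an adjusted p of 0.122 with an estimated correlation, with 0 of 25 called by edgeR over all genes and 6 higher and 2 lower when adjusted over the list alone. Ribosomal protein genes, median log2 -0.45, had a camera adjusted p of 1.18e-09 for lower levels and an adjusted p of 0.671 with an estimated correlation, and 0 of 78 were called by edgeR. These genes took 3.21% and 6.14% of counts in the 2 libraries at 24 h and 5.67% and 7.51% at 0 h (4.68 ± 2.07% and 6.59 ± 1.30%). For oxidative phosphorylation genes, 0 of 76 called, the camera adjusted p was 0.00768 and the adjusted p 0.868 with an estimated correlation. The other 17 lists were not called, the lowest adjusted p being 0.0729 for replication-dependent histones. The megakaryocyte list among them had a median log2 of 0.38 while camera's direction was down (adjusted p = 0.598).

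Among single genes PINLYP (ENSG00000234465, chromosome 19, 43575801 to 43583964) rose 7.62-fold from 5.28 ± 2.3 CPM, the axon guidance gene SLIT2 7.3-fold, ZFPM2 3.73-fold and the cohesin gene SMC1B 2.91-fold. PINLYP was nearly absent with the mutant construct at 0 h, so the cells differed in it before doxycycline and the mutant is a poor control for it. The Fc receptor gene FCGR1A, part of a family of near-identical genes, rose 3.69-fold from 6.8 ± 0.06 CPM. RUNX2 (ENSG00000124813, chromosome 6, 45328157 to 45664349), a transcription factor of bone formation, fell 3.42-fold from 12.7 ± 1.0 CPM. IKZF2 fell 2.53-fold, the myeloid factor CEBPA 2.39-fold, SNAI2 2.48-fold and the immediate early gene EGR1 2.18-fold. CDKN1A, the cell cycle inhibitor controlled by p53, fell from 2.33 ± 0.022 to 0.641 ± 0.17 CPM. PRF1 went from 0.402 ± 0.21 CPM to 0 counts, and no fold is given for it.

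In all, 510 of 15890 tested genes passed with the FAM46C construct, 296 higher and 214 lower, 97 by at least 2-fold. The test used a spread pooled over all 8 construct libraries; with only the 4 libraries of this construct 5 genes passed, and without 0 h replicate 1, 0 h replicate 2 or 24 h replicate 1 there were 5, 4 and 209. Scaling by total counts gave 205 higher and 250 lower genes, DESeq2 called 950 genes and edgeR without a count filter 1221.

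With the mutant construct 2 genes passed edgeR's quasi-likelihood test, TENT5C (20.4-fold, log2 4.35 ± 0.15) and FCGR1A, which rose 5.95-fold from 6.52 ± 1.0 CPM (adjusted p = 0.000112). KIT was at 912 ± 4.1 against 1049 ± 8.0 CPM and GATA2 at 624 ± 15 against 657 ± 15 CPM, neither past the test. Camera called 9 lists, 0 of which held with an estimated correlation (lowest adjusted p = 0.117). Targets of p53 had the lowest camera adjusted p, 1.31e-09 for lower levels at a median log2 of -0.19, with 3 of 26 lower when adjusted over the list alone. Cell cycle genes were called higher (3.02e-06) at a median log2 of 0.13, cholesterol synthesis (0.0015) and mast cell genes (0.00093) lower, and lysosome (0.023) and endoplasmic reticulum-targeted surface and secreted genes (0.0349) lower, all as camera adjusted p-values. Camera called the cell cycle and mast cell lists in the same direction with the FAM46C construct. Neither list was called for the difference of the responses, so these calls are not separated from doxycycline or 24 h of culture. The terminal maturation (0.00264) and poly(A) lists (8.81e-05) were called higher with TENT5C and had camera adjusted p-values of 0.998 and 0.59 without it, and the call of the granulocyte list (0.00444) had FCGR1A as its single called member and a median log2 of -0.26.

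The difference of the 24 h response between the constructs was tested directly. The labels do not say what the mutation does to FAM46C, and TENT5C stood lower with the mutant at 0 h (409 ± 9.8 against 809 ± 31 CPM) and at 24 h (8346 ± 800 against 12370 ± 340 CPM), so the test does not separate the mutation from the dose. No gene passed edgeR's quasi-likelihood test (lowest adjusted p = 0.258), and 1655 had an unadjusted p under 0.05. DESeq2 called 42 genes, edgeR without a count filter 102, and edgeR with a crossed pairing of replicates, chosen after the data were seen, 942. The difference was -0.40 ± 0.17 on the log2 scale for KIT, -0.42 ± 0.15 for GATA2 and 0.56 ± 0.18 for SLC4A1, with adjusted p-values of 0.316 to 0.462 in that test. In simulated data of this design the test found 83.9% of 4-fold and 34.2% of 2-fold differences of response. Camera called 12 lists, among them red cell membrane genes (adjusted p = 1.6e-07, median log2 0.37, 10 of 30 higher when adjusted over the list alone) and ATF4 response genes (3.88e-07, 7 of 30 higher when adjusted over the list alone). With an estimated correlation 0 of them held, the lowest adjusted p being 0.0842 for the red cell membrane, terminal maturation and cholesterol lists.

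The constructs differed already at 0 h, where 14 genes passed the test, 8 higher and 6 lower with FAM46C than with the mutant. TENT5C was 1.98-fold higher, ROBO2 2.95-fold and the collagen gene COL4A5 2.12-fold higher. PLS3, which bundles actin, was 9.87-fold lower (12.7 ± 1.4 CPM with the mutant and 1.29 ± 0.36 CPM with FAM46C), CYTL1 3.88-fold and SIGLEC6 2.04-fold lower. CDH19 was at 5.3 ± 0.82 CPM with the mutant and at 0 counts with FAM46C, and PINLYP at 0.0356 ± 0.050 CPM with the mutant and 5.28 ± 2.3 CPM with FAM46C, so no folds are given. Without FAM46C replicate 1 or 2 there were 7 genes each, and without mutant replicate 1 or 2 there were 4 and 5. Camera called 6 lists, 0 of which held with an estimated correlation (lowest adjusted p = 0.423), the interferon list (0.000188), globins (0.000726) and immediate early genes (0.0149) lower and endoplasmic reticulum chaperones (0.000188), lysosome (0.00932) and cell cycle genes (0.0192) higher with FAM46C.

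**Figure D4:**
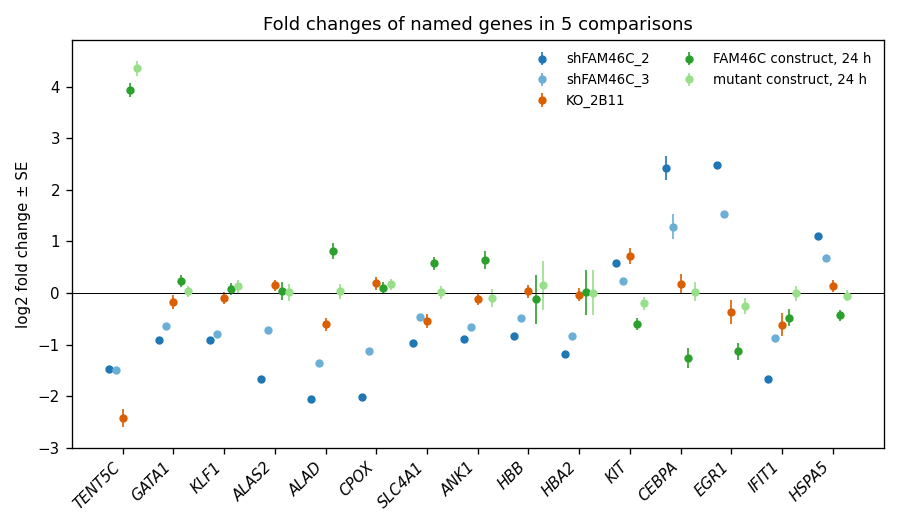
Log2 fold change with its standard error for 15 genes in 5 comparisons, with points for the fitted values and bars for the standard errors. ALAS2 and SLC4A1 lie below 0 in the knockdown, and SLC4A1 above 0 with the FAM46C construct, where KIT and CEBPA lie below 0.

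Genes called in the knockout were compared with those called with the FAM46C construct. The 0 h libraries were not in a state without FAM46C messenger RNA, TENT5C being at 809 ± 31 CPM there against 40.6 ± 2.1 CPM in WT and 7.55 ± 2.0 CPM in the knockout libraries. PGR also differed, at 73.8 ± 15 CPM at 0 h against 0.214 ± 0.097 CPM in the knockout libraries, so the comparison cannot show whether induction undoes the loss. Of 56 genes called in both, 26 (46.4%) had opposite signs, where independent lists would share 14.7, at an odds ratio of 0.843 (Fisher's exact test, two-sided p = 0.788). TENT5C was one of them, lower in the knockout and higher with the construct. KIT was another, higher in the clone and lower after induction, as was SLC4A1 in the reverse sense. ALAD, 1.53-fold lower in the clone, rose 1.75-fold with the construct. Hardly any genes were called in both without either FAM46C 0 h replicate, and the odds ratio was 1.45 without 24 h replicate 1. The number of opposite signs was 16 of 33 without knockout replicate 1 and 46 of 102 without WT replicate 3. Without 24 h replicate 2 it was 19 of 62, and opposite signs were then rarer than chance gives (odds ratio 0.21, Fisher's exact test, two-sided p = 0.00447).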

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

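The tests of interferon-stimulated genes in the knockout and between the hairpins were chosen only after the result was seen, as was the overlap of knockdown and FAM46C construct, which single genes had prompted. The bound used to read the interferon difference between the hairpins was also set after its value was known.

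A direct comparison of the hairpins, which lowered TENT5C alike, gave 7285 genes that differed, and 760 genes were called with both hairpins in opposite directions. By camera, genes higher with shFAM46C_3 than with shFAM46C_2 were ribosomal proteins (adjusted p = 2.26e-10), haem and iron (1.64e-07), interferon response (2.15e-07), red cell membrane (5.98e-06), ATF4 response (1.32e-05), globins (0.00712), endoplasmic reticulum-targeted genes (0.00712), lysosome (0.00737), erythroid transcription factors (0.0224) and glycolysis (0.0306). Cholesterol synthesis and immediate early genes were lower (3.18e-05 each). The last 2 held with an estimated correlation and the other 10 did not.

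The response to the FAM46C construct differed from that to the mutant, by camera on the difference itself, for 12 lists. It was higher for red cell membrane (adjusted p = 1.6e-07), ATF4 response (3.88e-07), cholesterol synthesis (1.98e-06), terminal maturation (0.000204), autophagy (0.0123), p53 targets (0.0123), lysosome (0.0235), histones (0.0394) and haem and iron genes (0.0424), and lower for ribosomal proteins (6.19e-09), oxidative phosphorylation (0.00425) and granulocyte genes (0.0339). With an estimated correlation 0 of them held, the lowest adjusted p being 0.0842. By camera, p53 targets and lysosome genes were called lower with the mutant construct, and granulocyte genes higher. None of these lists was called with the FAM46C construct.

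Other splits of the same libraries were counted for each comparison of 3 or more libraries per group. For the mean of both hairpins, 1 of 84 splits, the real one, gave as many genes in a two-group fit (5407, highest other 4247). The splits that broke up a group gave 0 or 1 genes, which shows only that replicates of a group lie close together. Only 3 splits keep the groups whole (5407, 4247 and 1696 genes), too few to exclude chance between whole groups. The highest other split set shFAM46C_2 apart from the rest, which points to a structure of the samples, the difference between hairpins. For shFAM46C_2 (8912 genes), shFAM46C_3 (7836), the difference between hairpins (7312) and the knockout (776), the real split was the 1 of 10 with as many, the highest other was 0, and 10 splits are too few for a share under 0.05.

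Genes changed in the knockout clone had no clear relation to the other experiments. A candidate explanation is that they are differences of clone 2B11 from WT that do not come from the loss of FAM46C, since 1 clone was compared. The odds ratio of same signs with the knockdown was 1.15 (Fisher's exact test, two-sided p = 0.434) but 1.42 (p = 0.000898) without WT replicate 3 and 0.633 (p = 0.00737) without WT replicate 1. The odds ratio of opposite signs with FAM46C induction was 0.843 (Fisher's exact test, two-sided p = 0.788) and 0.21 (p = 0.00447) without FAM46C 24 h replicate 2, but TENT5C was above WT at 0 h already, so this test cannot show whether induction undoes the loss. Neither value decides between clone differences and effects of FAM46C, which cannot be told apart with 1 clone, and loss of FAM46C stays open as a biological explanation. The control libraries also differed between experiments. TENT5C was at 39.33 to 43.0 CPM in WT, 76.59 to 81.59 CPM with the hairpins and 211.2 to 232.3 CPM with shGFP. Ribosomal protein genes took 15.6 ± 1.41% of counts in WT and 6.2 ± 0.14% with shGFP. Overlaps between experiments with such unlike controls say little about either explanation.

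Interferon-stimulated genes were lower than with shGFP in 35 of 40 with shFAM46C_2 and 27 of 40 with shFAM46C_3 (camera adjusted p = 6.25e-18 and 8.8e-09), with adjusted p-values of 0.0332 and 0.114 at an estimated correlation. A single high shGFP library is argued against, since the median log2 fold change was -0.919 at its weakest without 1 of them and -0.947 with all. In the knockout clone, where fewer of these genes were measured and some stood at low levels, the median was 0.049 (lower bootstrap bound over genes -0.064). The measured genes were thus not lower as a set in that clone. It is 1 clone that may differ in other ways, so this cannot decide whether any loss of FAM46C lowers these genes. A response to the shGFP vector cannot be told apart from the knockdown with 1 control hairpin, and the hairpins differed from each other by 0.615 in the median (-1.328 and -0.744 against shGFP). That difference lies below the distance of either hairpin from shGFP.

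Genes of the knockdown tended to move the other way after FAM46C induction, in 301 of 385 called in both (78.2%, independent lists 142.9, odds ratio 13.2, Fisher's exact test, two-sided p = 6.27e-29), KIT, ALAD, SLC4A1 and TENT5C itself among them. A hypothesis is that the FAM46C level moves these genes both ways, though induction started from a TENT5C level above WT. The number of shared calls rested on single libraries, and few genes were called in both without either FAM46C 0 h replicate. Without 24 h replicate 1 fewer genes were called in both, and the odds ratio was 13.6. Doxycycline or 24 h of culture stays open: of 1041 genes changed at least 2-fold in the knockdown, 65.4% had the opposite sign with FAM46C and 57.8% with the mutant, a difference of 7.6 percentage points (bootstrap interval 3.6 to 11.6), under the bound of 10 points set beforehand although the interval spans it and excludes 0. A single library as the sole cause of the direction is argued against, the lowest share without 1 library being 62.6%, though the mutant alone gave 57.8%. Leaving out 1 library at a time cannot tell whether replicate 1 of both FAM46C groups together set the direction. Genes are not independent, so these intervals and p-values are too narrow.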

How the results depend on the processing

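The crossed pairing, leaving out replicate 1 of both FAM46C construct groups, the lists without TENT5C and every setting of the overlap of knockdown and FAM46C construct were chosen after seeing the data. No named gene or list turned from a call to the other direction under any alternative run. The odds ratio of signs between knockout and knockdown, 1.15, was 0.633 without WT replicate 1 and 1.42 without WT replicate 3. Scaling by total counts turned the balance of higher and lower genes from 296 and 214 to 205 and 250 with the FAM46C construct, from 4134 and 3843 to 3951 and 4019 for shFAM46C_3, and from 3705 and 3580 to 3445 and 3955 between hairpins. The last also turned with DESeq2 (3540 and 3655), RLE factors (3599 and 3719), TMM without globin and mitochondrial genes (3604 and 3694) and no count filter (3502 and 3529). The balance for the mean of both hairpins, 4370 and 4440, turned with TMM without these genes (4441 and 4353) and no count filter (4392 and 4259). It also turned at a 2-fold threshold (701 and 691) and without shGFP replicate 2 (4044 and 4020). With the FAM46C construct the balance turned without 24 h replicate 2 as well. Other balances near even turned too, among them shFAM46C_2 and the knockout at a 2-fold threshold (774 and 1035, and 128 and 152). The knockdown counts stayed within 1.5 times except at a 2-fold threshold, while those of the construct experiment moved widely, and the cause was not tested.

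At a 2-fold threshold the counts were 1809 for shFAM46C_2, 1221 for shFAM46C_3, 1392 for their mean, 836 between hairpins, 280 in the knockout and 97 with the FAM46C construct, and the overlaps were 732 for both hairpins, 6 for knockout and construct, 26 for knockout and knockdown and 28 for knockdown and construct. DESeq2 gave 950 genes with the FAM46C construct, 12 with the mutant, 42 for the difference of responses and 58 at 0 h, and 52 and 524 for the construct's overlaps with knockout and knockdown. Without a count filter there were 1221, 14, 102 and 105 genes in these 4 comparisons. With only the groups compared there were 5 genes with the FAM46C construct and 6 with the mutant, where fewer libraries estimate the spread.

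Replicate numbers were not taken as pairs, since no label says so and in no groups of 3 did every same-numbered pair correlate over 0.1. Deviations of same-numbered libraries at 5 CPM or more correlated at -0.164 to 0.115 in the knockdown, -0.317 to 0.341 in the knockout, 0.615 and 0.541 within a construct and -0.514 to -0.604 between constructs, and over all tested genes at -0.059 to 0.036, -0.107 to 0.095, 0.14 and 0.102, and -0.089 to -0.144. In the knockdown 3 of 3 pairs of shGFP and shFAM46C_2 correlated best with their own number, 0 of 3 in the other pairs of groups, and 1 of 3 in the knockout. It was 2 of 2 within each construct and 0 of 2 between constructs, where 2 libraries per group make deviations mirror images. The replicate block gave 5 genes with the FAM46C construct, 8 at 0 h, and overlaps of 1 with the knockout and 2 with the knockdown. A crossed replicate block gave 3143 genes with the FAM46C construct, 12 with the mutant, 942 for the difference, 101 at 0 h, and overlaps of 112 and 1462.

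Without replicate 1 of both FAM46C groups there were 18 genes, and overlaps of 1 and 9. Leaving out 1 library gave 8231 to 8561 genes for shFAM46C_2, 7246 to 7656 for shFAM46C_3, 7924 to 8698 for their mean, 6544 to 6784 between hairpins, 382 to 2173 in the knockout, 4 to 625 with the FAM46C construct, 2 to 2 with the mutant, 0 to 0 for the difference and 4 to 7 at 0 h. The libraries that set the extremes were WT replicate 3 (2173) and knockout replicate 1 (382), FAM46C 24 h replicate 2 (625) and 0 h replicate 2 (4). Overlaps ranged from 4793 to 5156 for both hairpins, 1 to 46 for knockout and construct, 121 to 823 for knockout and knockdown and 2 to 345 for knockdown and construct. Where 1 library was left in a construct group, it was assumed to vary like the other groups.

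Camera calls of 15, 14, 13, 12, 7, 12, 9, 12 and 6 lists (shFAM46C_2, shFAM46C_3, their mean, between hairpins, knockout, FAM46C construct, mutant, difference, 0 h) became 7, 2, 7, 2, 0, 2, 0, 0 and 0 with an estimated correlation and 25, 28, 27, 21, 6, 9, 3, 5 and 0 with fry, which does not compare a list with other genes. Without TENT5C they were 11 with the FAM46C construct and 7 with the mutant. Of 45 genes looked at with the FAM46C construct, 29 lost their call with only the groups compared and 30 under the block. In each of these settings 5 genes passed among all tested. With total-count scaling 3 lost their call, and with DESeq2 2. Of 48 genes in the knockout, 4 lost their call with total-count scaling, 2 under the block and 1 without a count filter. Both sets hold genes not called in the main test, which had no call to lose. Summed over the refits that left out libraries, calls of these genes were lost 107 times with the FAM46C construct, 25 times in the knockout and 19 times at 0 h. The depth of these libraries limits genes near the floor of 3 counts.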

Other observations

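All values in this part were picked after they were seen. The list of glycolysis and hypoxia genes was not called in the clone or after FAM46C induction (camera adjusted p = 0.617 and 0.33), and 2 of its genes moved the same way in both. NDRG1, a hypoxia-responsive gene, rose 3.11-fold in the clone and 2.48-fold after induction, and the pyruvate kinase gene PKM fell 1.57-fold and 1.74-fold, while in the knockdown PKM rose 1.95-fold and NDRG1 fell (log2 -1.20 ± 0.08). In the clone ITGA2B rose 1.76-fold and RUNX1 1.8-fold. Among lysosomal genes GM2A fell 1.62-fold and GLA 1.52-fold in the clone, and CTSH rose 1.83-fold. TENT5A, the relative of TENT5C, rose 1.5-fold with the mean of both hairpins, from 25.1 ± 2.3 to 32.7 ± 2.1 and 43.3 ± 1.8 CPM.

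The 10 largest falls of the knockout clone were looked up in the other experiments as CPM scaled by total counts, a description across separately prepared libraries. GALNT14 had 0 counts in all construct libraries, where 3 counts over a group equal 0.0472 to 0.0501 CPM. CCDC22 held 0 counts in both mutant groups and 0.283 ± 0.039 CPM at FAM46C 0 h, and TMEM273 lay between 0.59 and 0.773 CPM. PGR differed, at 0.223 ± 0.11 CPM in the knockout libraries but 74.1 ± 14 CPM at FAM46C 0 h and 76.7 ± 5.3 CPM at mutant 0 h, above the 10.8 ± 2.5 CPM of WT. REC8 fell from 37.1 ± 3.4 to 1.56 ± 0.62 CPM in the clone, and stood at 27.0 ± 1.5 CPM with shGFP against 10.1 ± 0.65 and 9.94 ± 0.67 CPM with the hairpins. Of these 10 genes, 1 reached at least 50% of its WT level at FAM46C 24 h, 1 at FAM46C 0 h and 5 with shGFP. At both FAM46C times the gene was PGR, which was lower at 24 h (44.8 ± 9.9 CPM) than at 0 h.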
